A study of Homo sapiens with 3 samples.

How the data were processed

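The series holds 3 one-colour Agilent arrays of RNA from HGC-27 gastric cancer cells, taken 48 h after transfection with pcDNA3.1 control vector, with pcDNA3.1-GMAN or with pcDNA3.1-EphrinA1, with 1 array for each group per the labels. Per the file headers, each scanner file was made by Feature Extraction 11.0.1.1 with the protocol GE1_1100_Jul11 and grid 026652, whose probe names rest on hg19, and its signal columns hold intensity in scanner units, background subtracted by that software. All 3 arrays lie on 1 slide with 1 scan, so neither slide nor scan separates the groups. Position on the slide, culture and hybridisation cannot be told apart from group, with 1 array each.

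The table of values deposited by the authors holds 30304 probes on a log2 scale, not centred on a control, with an equal median of 8.49 on each array, which its values show to be quantile normalized; its further steps are not given in the sources used here. Its values correlate with the log2 scanner signals at r = 0.9997, 0.9997 and 0.9987 for the control, GMAN and EphrinA1 arrays. It leaves out 3823 probes, of which 0 were well above background on any array. The comparisons start from the scanner files, and the deposited log2 table enters as an alternative.

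Each array holds 43118 spots that are not controls, for 34127 probes: 33128 with 1 spot and 999 with 10. Spots well above background numbered 36275 (84.1%), 38385 (89.0%) and 33409 (77.5%) on the control, GMAN and EphrinA1 arrays, with median signals of 352, 324 and 261. Spots that the software marked as non-uniform or as deviating from their repeats, 332, 271 and 295, were left out, and 0 were saturated. The processed signal was set on a log2 scale, each array was shifted so that its 75th percentile (signals of 1939, 1804 and 1509) became 0, and spots of a probe were averaged. A gene takes the value of its brightest probe. A gene is measured in a comparison where its probe is well above background on both arrays, by more than 0.5 of its spots. Where it is so on 1 array only, the fold is given as a bound, written as at least. It is taken against the lowest signal well above background on the other array. Where the gene's own reading on that array is higher, that reading is used, and the bound is then the plain ratio. The limit is the lowest of the whole array, so these bounds are approximate and on the large side.

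Probes were matched to gene symbols by the accessions in the scanner files and the RefSeq gene table of assembly GRCh38.p14, used for names only; 25771 probes gained a symbol, for 19740 genes, of which 4994 have more than 1 probe, and 8356 probes gained none. The table gives GMAN as a synonym of EFNA1, and no probe could be assigned to GMAN itself. Of 692 entries in the gene lists, 679 have a probe.

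With 1 array per group there is no test: each comparison (GMAN over control, EphrinA1 over control, GMAN over EphrinA1) is a difference of log2 signals, and genes at least 2-fold apart are counted. The technical SD comes from repeated probes with at least 8 usable spots on both arrays, 842, 790 and 795 of them in the 3 comparisons. For a difference of single spots it has a median of 0.106, 0.0997 and 0.0970, and of 0.275, 0.255 and 0.249 in the lowest 25% of levels. A value after ± is the median SD at the level of the gene, divided by the root of its number of spots. It was not measured on the gene itself. The median of each of 29 gene lists, with at least 5 measured members, was placed among 10000 random lists of genes matched by level in 10 bins, as a description; a list is named as higher above percentile 97.5 and as lower under percentile 2.5. The choices up to here, the lists and 11 alternatives were written before the data were examined.

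Genes named in the report are the 12 largest differences each way among genes with a full symbol (no placeholder or antisense name), at a level above the lowest 25% of measured genes and with all their measured probes on the same side, the 4 largest bounds each way, up to 4 members of a list that are at least 1.5-fold apart, EFNA1, and up to 8 genes at least 2-fold apart on both plasmid arrays each way. Members of lists named as higher or lower are given as examples of the largest values. The same rule was applied to genes outside the clustered areas after the data were seen.

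Clustering on the slide was looked for in windows of 21 rows and 21 columns: a window with at least 5 spots and over 3 times the expected number of spots 2-fold apart is part of a clustered area, and counts were set against 1000 shuffles of position. These windows were chosen after the data were seen. They cover 6258 spots (14.5%).

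The alternatives were normexp background correction with offset 50 on median signals (mean signals are not among the columns used here), quantile normalization, median scaling and cyclic loess (limma 3.58.1, R 4.3.3), the processed values of the authors, genes well above background on all 3 arrays, no background filter, the brighter part of the genes, the mean over probes of a gene, and thresholds of 1.5-fold and 3-fold; 2 more, without the clustered areas and with the median over spots, were added after the data were seen. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

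The scripts were tested on simulated data with known differences. Genes set 3-fold and 4-fold apart were all called 2-fold, those set 2-fold apart in 62%, 40% and 54% of cases for the 3 comparisons, and those set 1.5-fold apart in 2%, 4% and 0%. Lists of genes drawn at random, with independent spot error and no difference, were called in 4%, 4% and 5% of cases. Such lists lowered by 0.1 were called in 86.5%, 92.5% and 93%. Planted local defects, of 68, 62 and 71 spots set 8-fold apart, were marked in 100% of their spots. Defects weaker than 8-fold were not tested. In the main area of spots lower with GMAN than on the control array, 109 of 3106 measured spots were at least 2-fold lower. The 100% therefore does not show that spots outside the clustered areas are free of defects. With no defect planted, 3.23%, 2.75% and 2.37% of the measured spots were marked.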

Results

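HGC-27 is an established line of human gastric carcinoma cells, and GMAN is a long noncoding RNA of gastric cancer. The series asks how gene expression differs 48 h after these cells receive a plasmid for GMAN or for ephrin-A1, a membrane-anchored ligand of Eph receptors, against the empty pcDNA3.1 vector. There is 1 array per group, so each comparison below is a difference between 2 arrays, with no replicate check and no test. The values after ± are technical SDs taken from repeated probes of like level, divided by the root of the number of spots. They are not the SD of a gene's own spots and cover technical error only. The number of arrays is what limits precision. Values called largest are so among genes above the lowest 25% of measured genes by level.

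EFNA1, the gene of ephrin-A1, was not higher on the array labelled EphrinA1 than on the control array. Its probe is spotted 10 times on each array, and 9 of the 10 spots were lower there, with a mean log2 difference of -0.13 (SD between spots 0.10; -0.07 without its spots in the clustered areas described below). On the GMAN array EFNA1 lay close to the control level, at -0.03 (SD 0.09). Between the 2 plasmid arrays it was higher with GMAN by 0.10 (SD 0.06) on 10 of 10 spots. Among all measured genes, EFNA1 lay at percentile 34.1 for EphrinA1 over control, 52.3 for GMAN over control and 65.7 for GMAN over EphrinA1. These differences did not set EFNA1 apart from other genes, and its spots are repeats on single arrays. The position of this probe relative to the insert of the plasmid is unknown, and if it lies outside the insert it checks nothing about the transfection. GMAN itself has no identified probe on this array, so the GMAN level cannot be read from these data.

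**Figure D1:**
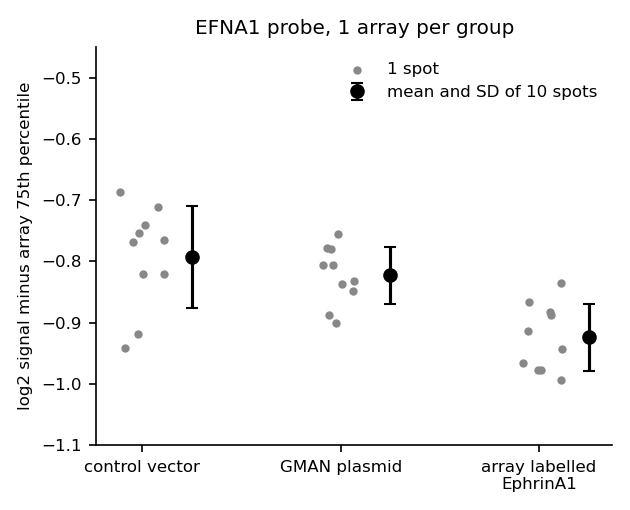
EFNA1 signal on a log2 scale, minus the 75th percentile of the array (vertical axis), on the control, GMAN and EphrinA1 arrays; each point is 1 of the 10 spots of its probe. The mean was -0.79 on the control array, -0.82 on the GMAN array and -0.92 on the array labelled EphrinA1.

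Spots that differ at least 2-fold between arrays cluster in some places on the slide. Of the 104 spots at least 2-fold higher on the array labelled EphrinA1 than on the control array, 47 lay in a block that holds 1.03% of the spots measured, among them the probes of SPMAP1, KRT33B and KDR. Of the 237 spots at least 2-fold lower on the GMAN array than on the control array, 109 lay in an area that holds 8.72% of the spots. DEFB129, a beta-defensin gene with 10 spots, has spots on both sides of its edge: the 4 inside were lower by log2 -1.04 to -1.65, and the 6 outside by -0.08 to -0.36. These clustered areas, chosen after the data were seen, hold 14.5% of all spots, and single-spot genes that lie in them are marked below.

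**Figure D2:**
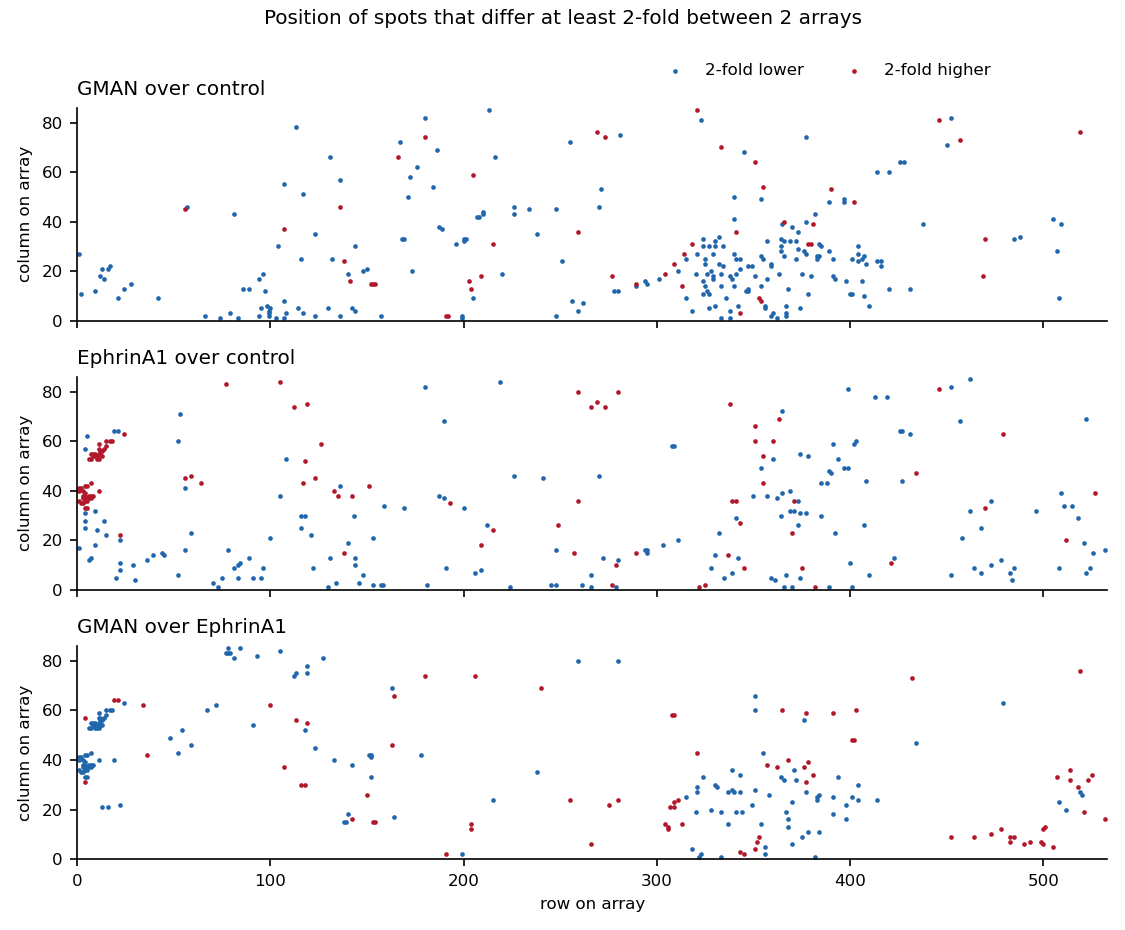
Position on the array (horizontal axis, row number; vertical axis, column number) of spots at least 2-fold higher (red) or lower (blue) in each comparison; each point is 1 spot. The densest window held 28 spots for GMAN against control, 36 for EphrinA1 against control and 40 for GMAN against EphrinA1, where shuffled positions gave at most 14, 15 and 13.

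With GMAN, few genes stood far from the control array: 97.1% of 17108 measured genes lay within 1.5-fold, 20 were at least 2-fold higher and 102 at least 2-fold lower (5 and 16 under normexp, and 43 lower without the clustered areas). The clearest higher values were those of YWHAE, which encodes the epsilon isoform of the 14-3-3 adaptor proteins, at log2 1.19 ± 0.11 (2.29-fold), its pseudogene YWHAEP1 at 1.16 ± 0.11, and ANKRD36BP1, a pseudogene, at 1.73 ± 0.11 (3.31-fold). Among the lower genes outside the clustered areas were S100A6, a calcium-binding protein gene, at -0.90 (1.87-fold), GCNT2, the enzyme that makes the branched I blood group antigen, at -0.82 (1.76-fold), and GDF15, a stress-induced cytokine, at -0.71 (1.64-fold).

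Higher with GMAN were also SERTAD3, a cell cycle regulator, at 1.02 ± 0.11 (2.03-fold), VAV2 at 0.99 ± 0.09 (1.99-fold), and CLDN6, a tight junction claudin of embryonic epithelia, at 0.88 ± 0.11 (1.84-fold). HERC1 (0.87 ± 0.10), STAB2 (0.86 ± 0.11) and POF1B (0.91 ± 0.11) followed, though the mean over its probes put POF1B at -0.18. No other probe of POF1B counted as measured in this comparison, so that mean does not show a reversal. The translation factor gene EIF5A was higher at 1.04 ± 0.27, metallothionein MT1F at 0.65 ± 0.11 (1.57-fold), and NKG7, a granule protein gene of cytotoxic lymphocytes, at 0.72 ± 0.27. Some genes were well above background on 1 of the 2 arrays only, which gives a lower bound of the fold: FAM230C was at least 3.60-fold and GLB1L3 at least 3.53-fold higher.

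Of the 12 largest lower values with GMAN, 11 lie in clustered areas. Among these, HSPA6, a stress-inducible heat shock gene, read -1.37 ± 0.11 while its other probe read -0.03, and BCL2L11, which encodes the apoptosis promoter BIM, read -0.99 ± 0.09 while its 2 other probes averaged -0.07. The epithelial splicing regulator ESRP1 (-1.45 ± 0.27) and the epithelial transcription factor gene GRHL2 (-0.62 ± 0.27) were lower inside such areas too. Without them GRHL2 read 0.11, from another probe that did not count as measured, so this value cannot check the lower one. Outside them, the neuropeptide gene PTH2 (-0.94) and PGM2L1 (-0.88) were lower. The chemokine gene CCL5 was lower by -1.09 ± 0.27, the antiviral OAS3 by -0.93 ± 0.27 (its other probe, -0.27) and the nucleic acid sensor ZBP1 by -0.66 ± 0.27. Bounds put IFNK, an epithelial interferon gene, at least 12.7-fold and RPL39L at least 7.29-fold lower.

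Of the 29 gene lists, 5 stood above the central 95% of matched random lists with GMAN and 0 below it. The largest median was that of YAP and TGF-beta target genes, at 0.07 (9 of 15 higher, among them ID3 0.28, TGFB1 0.23 and LATS2 0.22), which read -0.00012 with no background filter. Heat shock genes followed at 0.05 (9 of 14 higher, BAG3 0.23; the mean, with HSPA6, was -0.06), then proteases at 0.03 (14 of 27, with MMP16 0.38 and, in a clustered area, MMP14 0.42), which read -0.020 when probes of a gene were averaged. Hypoxia-induced genes stood at 0.03 (13 of 20 higher) and mitotic genes at 0.01 (14 of 27 higher, MKI67 0.37), the latter at -0.0043 under normexp and -0.0014 under median scaling. None of the 5 kept this place under all alternatives. For lists of unrelated genes, 1.45 of 29 would fall outside this range, and 4.35 of the 87 results of all 3 comparisons, of which 23 did. Members of a list can vary together and the 3 comparisons share arrays, so these numbers are no expected count for the lists used here.

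**Figure D3:**
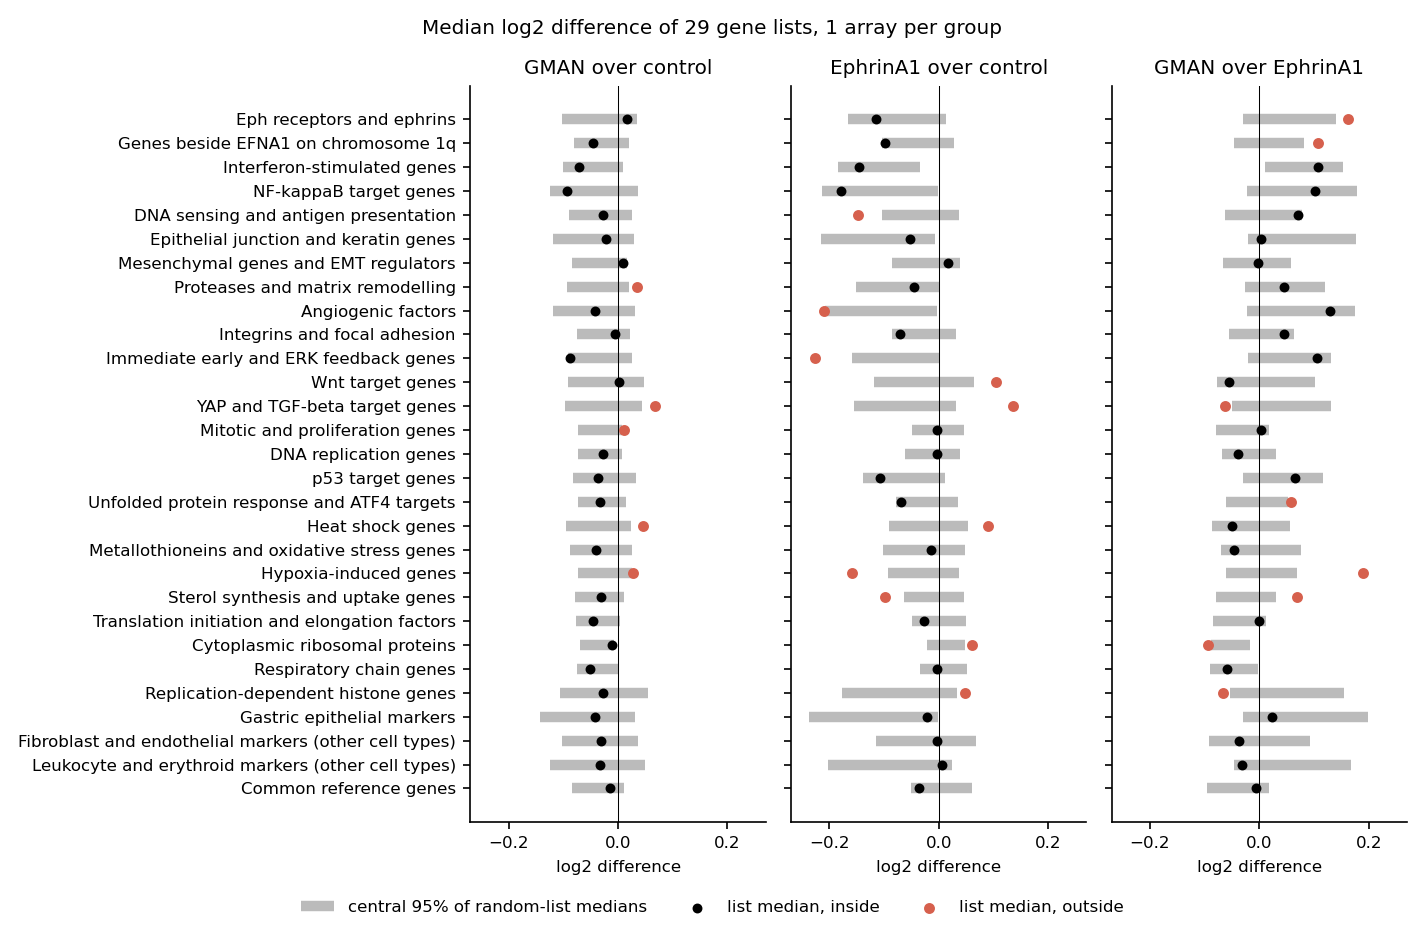
Median log2 difference (horizontal axis) of each gene list (vertical axis) in the 3 comparisons; points are list medians and bars span the central 95% of 10000 matched random lists. Hypoxia-induced genes stood at 0.03 for GMAN over control, -0.16 for EphrinA1 over control and 0.19 for GMAN over EphrinA1.

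On the array labelled EphrinA1, the list medians of hypoxia-induced genes and of immediate early and ERK feedback genes were lower than on the control array. The median of the joint list of YAP and TGF-beta targets was higher. The immediate early list kept its place under 10 of 11 alternatives. NDRG1, a hypoxia- and stress-induced gene, was lower by log2 -1.03 ± 0.10 (2.04-fold) and CA9, a carbonic anhydrase gene induced by hypoxia, by -0.89 ± 0.10 (1.85-fold). GCNT2 had the largest lower value, at -2.38 ± 0.10 (5.21-fold), and GDF15 read -0.93 ± 0.10 (1.91-fold). EFNA1 was not higher on this array, as given above, so nothing here shows that ephrin-A1 was made.

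Of 16019 measured genes, 95.5% lay within 1.5-fold, 55 were at least 2-fold higher and 84 at least 2-fold lower; cyclic loess gave 81 and 9, normexp 44 and 4, and leaving out the clustered areas 16 and 61, so these counts hang on the processing. The 12 largest higher values, 36.0-fold to 218-fold, all lie in clustered areas; they include SPMAP1, KRT33B, a hair keratin gene, CALCR, the calcitonin receptor gene, and KDR, a receptor gene for VEGF, at 52.8-fold. Outside these areas LYNX1, a modulator of nicotinic receptors, was higher at 1.62 (3.07-fold), YWHAE at 1.60 ± 0.10 (3.04-fold), YWHAEP1 at 1.55 ± 0.10 and SERAC1, a gene of phospholipid remodelling, at 2.83-fold. HBB, the beta-globin gene, was higher on 10 of 10 spots, at 2.05 with an SD between spots of 0.18 (4.14-fold), at a low signal of 145 against 45.2 on the control array. SERTAD3 (0.83) and HERC1 (0.89), both also higher with GMAN, were higher as well. So were TFAP4 (0.75), a transcription factor gene, and DKK1 (0.71, 1.64-fold), a secreted Wnt antagonist gene.

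Lower on the array labelled EphrinA1 were also ADARB2 (-1.04 ± 0.10; its other probe, -0.37), the protocadherin gene PCDHA5 (-0.93 ± 0.09) and, in clustered areas, GPR26 (-1.12 ± 0.10) and RAB41 (-1.02 ± 0.10). The tight junction genes CLDN1 (-0.80 ± 0.26) and OCLN (-0.72 ± 0.26), the cell cycle inhibitor CDKN1A (-0.63 ± 0.26), OAS3 (-1.20 ± 0.26) and the T cell receptor component CD3E (-0.64 ± 0.10) were lower, and the inflammatory cytokine gene IL1B read -0.77 ± 0.08 over 10 spots. The defensin gene DEFB104B was at least 11-fold lower by its bound. LGI1, SOX7 and GAD2 were at least 254-, 228- and 228-fold higher by their bounds, all 3 in clustered areas. For LGI1 and SOX7 this is the plain ratio to a control reading that was not well above background.

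Hypoxia-induced genes had a median of -0.16 (15 of 20 lower, with ENO2 -0.39, P4HA2 -0.34, PDK1 -0.33 and, in a clustered area, VEGFA -0.33), at percentile 0.02 of matched random lists. Immediate early and ERK feedback genes stood at -0.23 (20 of 24 lower, 4 of them by 1.5-fold: PHLDA1 -0.81 ± 0.26, FOS -0.73 ± 0.10, EGR1 -0.67 ± 0.10 and FOSB -0.60 ± 0.26), though FOSB read 0.15 under normexp and the list median -0.05 in the brighter part of the genes. Genes of DNA sensing and antigen presentation stood at -0.15 (15 of 18 lower, PSMB9 -0.23 and, in a clustered area, HLA-B -0.24) and sterol synthesis genes at -0.10 (19 of 22 lower, LSS -0.23, SCD -0.21, HMGCS1 -0.21). Angiogenic factors, which share VEGFA with the hypoxia list, had a median of -0.21 (15 of 19 lower, VEGFC -0.55) and a mean of 0.12, and they kept this place under 1 of 11 alternatives.

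YAP and TGF-beta targets stood at 0.14 on the array labelled EphrinA1, above all matched random lists (11 of 15 higher, among them the inhibitors of differentiation ID1 0.44, ID2 0.38 and ID3 0.30, and SMAD7 0.37). Wnt targets stood at 0.11 (7 of 11 higher, with DKK1, BAMBI 0.37 and NKD1 0.35), heat shock genes at 0.09 (11 of 14 higher, HSP90AA1 0.29, BAG3 0.25) and replication-dependent histone genes at 0.05 (9 of 13 higher). Ribosomal protein genes stood at 0.06 (35 of 42 higher) and turned to -0.03 under quantile normalization and with the processed values of the authors. Across the 10 lists outside the central 95%, 6 kept their place under every alternative.

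**Figure D4:**
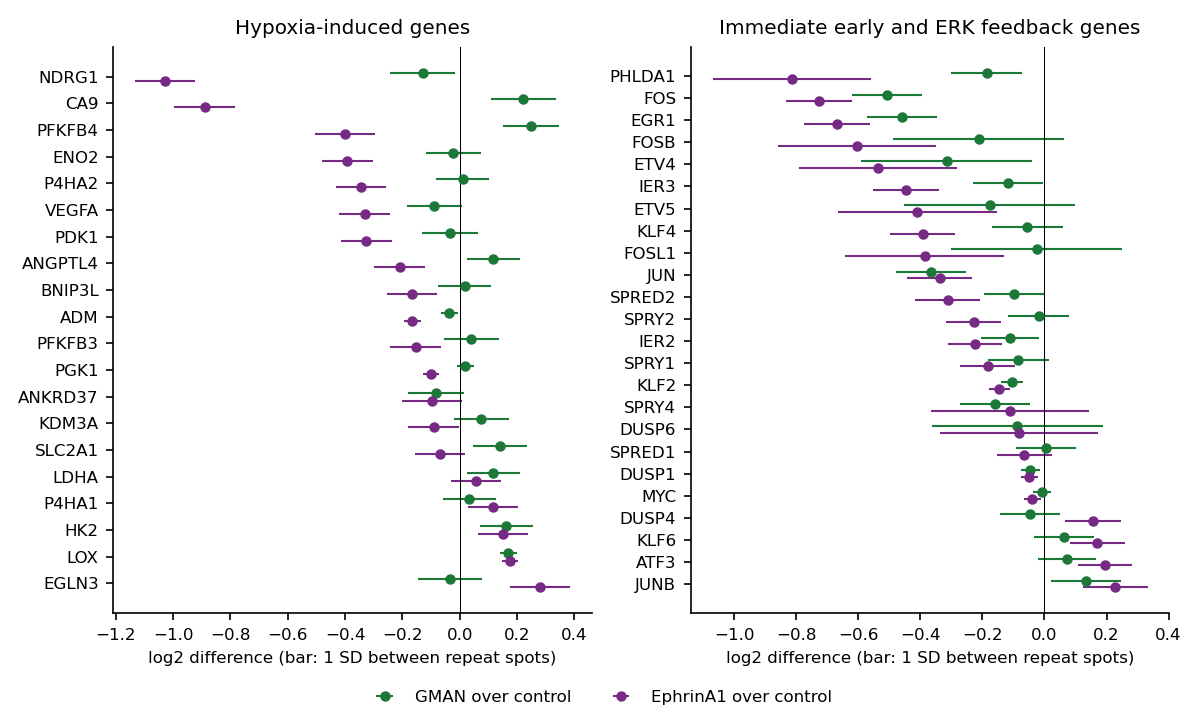
Log2 difference (horizontal axis) of each hypoxia-induced gene and each immediate early or ERK feedback gene (vertical axis) for GMAN over control (green) and EphrinA1 over control (purple). Points are genes and bars are 1 technical SD, taken from repeated probes of like level as for values after ±. NDRG1 stood at -1.03, CA9 at -0.89 and FOS at -0.73 for EphrinA1 over control.

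Between the plasmids, hypoxia-induced genes were higher with GMAN than on the array labelled EphrinA1, and GCNT2 had the largest higher value, at log2 1.56 ± 0.10 (2.96-fold). CA9 was higher by 1.11 ± 0.10 (2.16-fold), NDRG1 by 0.90 ± 0.10 (1.87-fold) and PFKFB4, a glycolysis regulator induced by hypoxia, by 0.65 ± 0.10 (1.57-fold), the last in a clustered area. NKX2-1, a lung and thyroid transcription factor gene, at 1.18 ± 0.10 (2.27-fold) and STAB2, a scavenger receptor gene, at 1.16 ± 0.10 (2.24-fold) were higher with GMAN too. Of 16051 measured genes 96.9% lay within 1.5-fold, 28 were at least 2-fold higher with GMAN and 82 at least 2-fold lower. Normexp gave 1 and 54, cyclic loess 14 and 121, and leaving out the clustered areas 20 and 18.

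The 12 largest lower values with GMAN against EphrinA1, 59.3-fold to 267-fold, all lie in clustered areas; in the same places IL32, a proinflammatory cytokine gene, read -6.43 ± 0.09 while its other probe read -0.06. Outside them LYNX1 (-2.0), SERAC1 (-1.53), DKK1 (-0.85, 1.80-fold) and EVPL (-0.90), which encodes envoplakin, were lower with GMAN. The claudin gene CLDN2 (0.76), CLDN1 (0.84 ± 0.25), OCLN (0.72 ± 0.25), CDKN1A (0.68 ± 0.25), PHLDA1 (0.63 ± 0.25), TAGLN (0.66 ± 0.10; its other probe, 0.17) and MMP24 (0.65 ± 0.25) were higher. IL1B was higher by 0.61 ± 0.08 in the main processing and read -0.05 under normexp. By bounds LMOD1 was at least 5.25-fold and EYA2 at least 3.89-fold higher, and GLRA2 at least 11.1-fold lower.

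Hypoxia-induced genes had a median of 0.19 (17 of 20 higher), above all matched random lists, and sterol synthesis genes stood at 0.07 (17 of 22 higher). Eph receptors and ephrins stood at 0.16 (15 of 18 higher, with EPHA8 0.47, EFNA3 0.38 and EPHA2 0.36), genes beside EFNA1 on chromosome 1q at 0.11 (17 of 25 higher), and unfolded protein response and ATF4 targets at 0.06 (16 of 27 higher). Lower with GMAN were YAP and TGF-beta targets at -0.06 (10 of 15 lower), histone genes at -0.07 (9 of 13 lower) and ribosomal protein genes at -0.09 (35 of 42 lower), which turned to 0.02 under quantile normalization and with the processed values of the authors. Of these 8 lists, 3 kept their place under every alternative: hypoxia, sterol synthesis, and YAP and TGF-beta targets.

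Both plasmid arrays shared a few genes that stood at least 2-fold from the control array. Higher on both were 6 genes, among them YWHAE and YWHAEP1, with values given above. PTPRZ1, a receptor phosphatase gene, stood at 1.95 ± 0.27 with GMAN and 2.07 ± 0.26 on the array labelled EphrinA1. HOXB8 stood at 1.73 ± 0.27 and 1.48 ± 0.26, and EIF5A at 1.04 ± 0.27 and 1.41 ± 0.26. ANKRD36BP1 stood at 1.73 ± 0.11 and 1.68 ± 0.26. Lower on both were 15, among them LINC01346 (-2.27 ± 0.27 and -2.39 ± 0.26) and FAM223B (-1.51 ± 0.11 and -2.12 ± 0.26). The kallikrein gene KLK9 (-1.36 ± 0.27 and -1.40 ± 0.26) was another. So was, in clustered areas, FOXJ1 (-1.84 ± 0.27 and -1.34 ± 0.26), a transcription factor gene of ciliated cells. The SDs of 0.26 and 0.27 are those of dim probes. These counts hang on the processing. Normexp gave 3 higher and 2 lower on both, and cyclic loess 8 and 6. Leaving out the clustered areas gave 6 and 9, and the brighter part of the genes 0 and 0. Among the 16014 genes measured on all 3 arrays 13 were higher and 59 lower with GMAN, and 54 higher and 83 lower on the array labelled EphrinA1; independent sets of these sizes would share 0.0438 and 0.306 genes, a value that leaves out the common control array. Across these genes the 2 differences correlated at r = 0.346 with 67.2% of genes on the same side, against r = 0.503 from spot error and the common control in 100 simulations; without the clustered areas r was 0.519 across 14292 genes, against 0.497 simulated for those genes (0.476 to 0.520). With the clustered areas included, the covariance was 0.0220 against 0.0120 simulated. The simulation drew spot error at the median SD of each level, which leaves out the noisier probes, so this gap does not measure a shared effect. The control array enters both differences and, as a single array, cannot be split, so shared values can come from it.

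**Figure D5:**
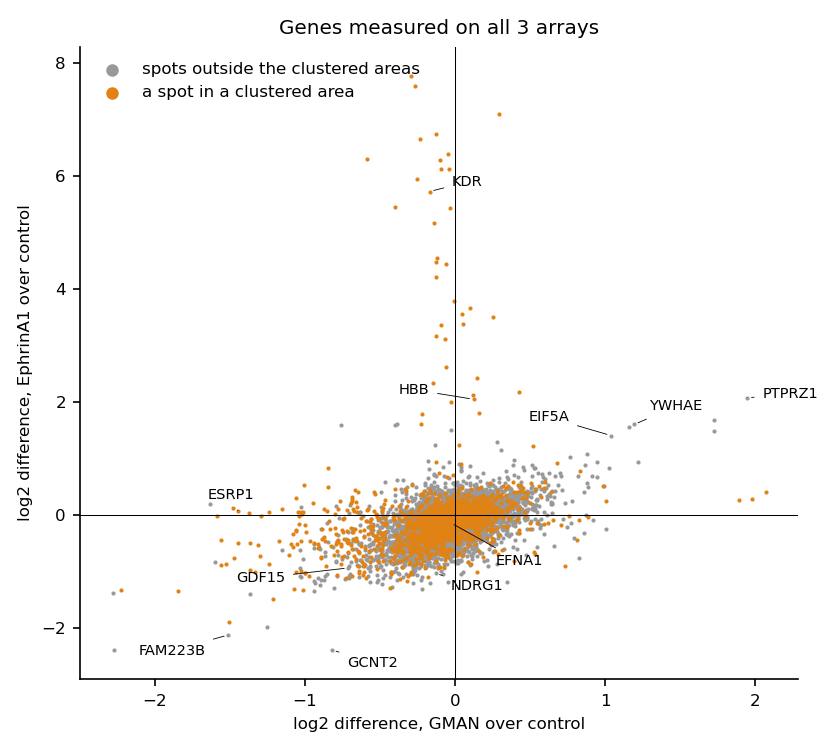
Log2 difference of GMAN over control (horizontal axis) against EphrinA1 over control (vertical axis); each point is 1 of 16014 genes, orange where a spot lies in a clustered area. The correlation is r = 0.346, and 6 genes are at least 2-fold higher and 15 at least 2-fold lower on both arrays.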

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

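Probes without a gene symbol, which no comparison uses, also differed outside the clustered areas: 10 were at least 2-fold higher and 50 lower on the GMAN array than on the control array, and 14 higher and 28 lower on the array labelled EphrinA1. Of the tests below, all but those of the hypoxia-induced genes were chosen after the result was seen. For the hypoxia-induced genes the predictions were written before, but the clustered areas left out there were themselves chosen after the data were seen.

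Genes at least 2-fold higher on the array labelled EphrinA1 than on the control array, 55 in number, cluster on the slide. Up to 36 such spots lay near 1 spot, against at most 9 in 1000 shuffles. A higher transcript level is therefore excluded as the source of that cluster as a set, though not for each gene. Of the 55 genes, 39 lie in clustered areas, which were marked in any of the 3 comparisons. Some of the 39 can lie outside that cluster, and for these the count of spots decides nothing. For 6 of the 39, 7 other probes spotted outside had a median log2 difference of -0.102, which fits a local defect; 4 of these probes are dim, and of the other 3, for 3 genes, 0 percent were 2-fold higher. HBB is different: its lowest spot among 8 outside the areas stood at 1.715, which excludes a local defect for HBB. For 15 genes outside the areas measured by 1 spot, with no other probe to compare, a higher transcript level stays open.

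The 102 genes at least 2-fold lower on the GMAN array than on the control array lie for the most part in such areas too, 62 of them. Up to 28 such spots lay near 1 spot, against at most 13 in 1000 shuffles, so a lower transcript level with GMAN is excluded as the source of that cluster as a set, though not for each gene. Some of the 62 can lie in areas marked through another comparison. For 8 of the 62, 9 other probes spotted outside, 7 of them dim, had a median of -0.012 (-0.474 to 1.53). This median fits a local loss of signal, at single spots only. The 3106 measured spots of the main area had a median of -0.039, against -0.037 for all measured genes, so the area as a whole was not lower. Of the 109 lower spots in the main area, 89 were also measured on the array labelled EphrinA1. Their median was -0.88 for GMAN over EphrinA1 and -0.36 for EphrinA1 over control, so part of the difference is not confined to the GMAN array. These spots were picked by a low value against the control array, which enters the last median too. Of the 102 genes, 87.25% lie in the lowest 25% by level; outside the areas 27 genes in that part lay 2-fold below its median and 17 above, a ratio of 1.59, which cannot tell symmetric scatter of dim probes from a lower level. For the genes outside the areas a lower transcript level and scatter therefore both stay open.

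Hypoxia-induced genes were lower on the array labelled EphrinA1 than on the control array. Cyclic loess left the median at -0.1424, which excludes an intensity-dependent trend. Leaving out the clustered areas gave -0.1393, which excludes the spots in those areas as the cause. The areas were marked by spots 2-fold apart, so a weaker regional difference between the arrays would not be marked and stays open. A difference between cultures or hybridisations cannot be told from an effect of the plasmid with arrays per group at 1. EFNA1 was not higher on that array, so the plasmid may or may not have raised ephrin-A1.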

How the results depend on the processing

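Of 1524 values of 159 results on named genes under the alternatives, 1197 kept direction and size, 317 moved and 10 reversed; of 949 values of 87 list results, 850 kept their sign and 756 stayed within the SD of matched random lists. A list counts as reversed only where its median was outside the central 95% of random lists and at least 0.08 from 0, which left 2 reversed. EFNA1 stayed within its SD between spots under each alternative that gave it a value; the brighter part of the genes gave none for EphrinA1 over control and GMAN over EphrinA1. No paired analysis was possible because each group is 1 array with no number shared between groups, and no array could be left out for the same reason. Leaving out the clustered areas and taking the median over spots were added after the data were seen. Signal over background limits the counts of dim genes: the technical SD in the lowest 25% of levels was 0.275 for GMAN over control, against a median of 0.106. Scalings moved the median of all genes by less than 0.1.

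Counts of genes at least 2-fold apart were 20 higher and 102 lower for GMAN over control, 55 and 84 for EphrinA1 over control, 28 and 82 for GMAN over EphrinA1, and 6 and 15 for both plasmids over control, with r = 0.346 between the 2 differences from control. The values that moved by more than 1.5 times, or for r lay outside its interval across genes, follow by alternative, and the cause was not tested except where stated.

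Under normexp GMAN over control had 5 higher and 16 lower, EphrinA1 over control 4 lower, GMAN over EphrinA1 1 higher and 54 lower, both plasmids 3 higher and 2 lower, and r was 0.285. Quantile normalization gave 35 higher for GMAN over control (89 lower), 14 lower for EphrinA1 over control (81 higher), 15 higher for GMAN over EphrinA1 (121 lower) and 7 lower on both; the processed values of the authors gave 35, 14, 15 and 7 for the same counts. Cyclic loess gave 9 lower for EphrinA1 over control, 14 higher for GMAN over EphrinA1, 6 lower on both and r = 0.309.

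Genes well above background on all 3 arrays gave 13 higher and 59 lower for GMAN over control, with fewer genes by construction. No background filter, which by construction adds dim genes, gave 234 higher and 326 lower for GMAN over control, 141 and 1224 for EphrinA1 over control, 997 and 267 for GMAN over EphrinA1, 33 and 200 for both, and r = 0.374. The brighter part of the genes, fewer by construction, gave 0 and 6, 21 and 0, 0 and 31, and 0 and 0 in the same order, with r = 0.325. The mean over probes gave 134 lower for EphrinA1 over control, 55 higher for GMAN over EphrinA1, 24 lower on both and r = 0.371.

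Without the clustered areas, fewer spots by construction, GMAN over control had 43 lower, EphrinA1 over control 16 higher, GMAN over EphrinA1 18 lower, both plasmids 9 lower, and r was 0.519. The lower threshold of 1.5-fold gave by construction 98 and 394, 120 and 601, 297 and 205, and 24 and 102 in that order. At 3-fold there were 6 and 21 for GMAN over control, 5 lower for EphrinA1 over control, 5 and 45 for GMAN over EphrinA1, and 2 and 1 for both.

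By these rules the reversed values were as follows. Ribosomal protein genes for GMAN over EphrinA1 stood at 0.0198 under quantile normalization and 0.0204 with the values of the authors, against -0.09. Under normexp FOSB for EphrinA1 over control was 0.15 and IL1B for GMAN over EphrinA1 -0.0515. The mean over probes put POF1B for GMAN over control at -0.18. Without the clustered areas another probe or fewer spots stand for the gene: DRC11 was 0.31 for EphrinA1 over control and -0.71 for GMAN over EphrinA1, GAD2 -0.87 and NIBAN3 -0.90 for EphrinA1 over control, NIBAN3 1.26 and HSPA6 0.10 for GMAN over EphrinA1, and GRHL2 0.11 for GMAN over control. For POF1B, DRC11, GAD2, NIBAN3 and GRHL2 no other probe counted as measured in the comparison, so these values do not show a reversal. Of the lists outside the central 95% of random lists, the smaller medians that also changed sign were ribosomal protein genes for EphrinA1 over control (-0.03 under quantile normalization and with the values of the authors) and, for GMAN over control, proteases (-0.020, mean over probes), YAP and TGF-beta targets (-0.00012, no background filter) and mitotic genes (-0.0043 under normexp, -0.0014 under median scaling).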

Other observations

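Among genes with 10 spots, picked here after their values were seen, several differed on every spot. By the median over spots, 0 of 774 such genes were at least 2-fold higher or lower for GMAN over control. For EphrinA1 over control, 1 of 737, HBB, was 2-fold higher and 0 were 2-fold lower, with 14 lower by 1.5-fold. Among all measured genes, 0.71% and 0.87% were 2-fold apart in these 2 comparisons. CXCR4, a chemokine receptor gene that hypoxia induces, was lower on the array labelled EphrinA1 than on the control array at log2 -0.64 (SD between spots 0.10) and lay at -0.04 with GMAN. MAFF, a small Maf transcription factor gene, read -0.75 (SD 0.21) on the array labelled EphrinA1 and -0.24 (SD 0.12) with GMAN. SUMF2 was higher on both, at 0.60 (SD 0.19) with GMAN and 0.59 (SD 0.20) with EphrinA1. DDIT4, a stress-induced inhibitor of mTOR, was higher with GMAN than on the array labelled EphrinA1, at 0.41 (SD 0.05).

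Most other gene groups lay within the range of matched random lists in the comparisons with control. Interferon-stimulated genes had medians of -0.07 with GMAN (26 of 39 lower) and -0.15 on the array labelled EphrinA1 (27 of 35 lower), NF-kappaB targets -0.09 and -0.18, p53 targets -0.04 and -0.11, and Eph receptors and ephrins 0.02 and -0.11. Epithelial junction and keratin genes stood at -0.02 and -0.05, mesenchymal genes at 0.01 and 0.02, integrins at -0.0056 and -0.07, and gastric epithelial markers at -0.04 and -0.02. DNA replication genes stood at -0.03 and -0.0027, respiratory chain genes at -0.05 and -0.0039, translation factors at -0.05 and -0.03, and metallothioneins at -0.04 and -0.01. Fibroblast and endothelial markers stood at -0.03 and -0.0026, leukocyte and erythroid markers at -0.03 and 0.0060, and common reference genes at -0.02 and -0.04.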
